A study of Rattus norvegicus with 2 samples.

How the data were processed

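Gene expression was measured in A7r5 cells, an established line of smooth muscle cells from embryonic rat aorta that is widely used as a model of the vessel wall. Per the labels' protocols, cells were infected for 72 hours with an adenovirus carrying the human cDNA of GLUT1, the facilitative glucose transporter encoded by SLC2A1, or with an empty adenovirus. The multiplicity of infection was 10, where a multiplicity of 1 stood for 100 particles per cell, and the medium of the arrayed cells held 5.5 mM glucose. Per the labels, RNA was isolated on 3 separate days and pooled into 1 sample per condition, and 5 µg of total RNA was turned into biotin-labelled cRNA. Each pool was hybridised to 1 array. The series therefore holds 2 arrays, 1 per group.

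The deposited table gives 1 linear intensity per probe set and array for 15923 probe sets, of which 57 are manufacturer's controls. All deposited intensities are whole numbers, and 3.01% of the control array's and 3.04% of the GLUT1 array's values are at or below 0. The sorted intensities of both columns differ by a median of 1 unit, and both have a median of 508 and quartiles of 175 and 1507.5, so the deposited values had already been made nearly equal in distribution between the arrays. The mean was 1500 on the control array and 1497 on the GLUT1 array. The software, the summary method, the background correction and the between-array method are not given in the sources used here. Detection calls were not used here, so a dim value has no call of present or absent behind it. Values rounded to whole numbers and forced to one distribution cannot show a change in the total amount of mRNA.

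Probe sets were named from the platform annotation, with symbols updated through the gene ID in a current rat gene table (assembly GRCr8). A single gene was listed for 12783 probe sets, several genes for 312, and none for 2771. The gene ID was in the current table for 12748 of the 12783. Probe sets with several genes or none were left out of gene counts, and several genes on the fixed lists were not named by any usable probe set and are not reported here. A gene was represented by its probe set with the highest mean log2 intensity over both arrays.

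The GLUT1 array was scaled so that the median log2 ratio over the brighter probe sets was 0, a shift of -0.00095 log2 units in the deposited values. Intensities at or below the 25th percentile of both arrays together, 175, were set to that floor, and log2 was taken. A gene counted as measured when its mean log2 value reached the median of all probe sets, 8.99 (an intensity of 507). This kept 7962 probe sets and 6114 of 10411 genes. A gene's difference is its log2 ratio, GLUT1 over control. A gene was called higher or lower at a ratio of 2-fold, a log2 ratio of 1 either way.

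With 1 pooled sample and 1 array per group there was no replicate check, and no p-value, standard error or significance call was computed for any gene. The number of arrays limits the precision. The pooling of 3 days also hides how far the days differed. Within-array precision was described in 2 ways. Genes with at least 2 measured probe sets, of which the 2 brightest were compared, gave an SD of a single log2 ratio. It was the SD of the difference between those probe sets divided by the square root of 2. The local spread of a probe set was the median absolute deviation, scaled to the SD of a normal distribution, of the log2 ratios of the 501 measured probe sets nearest to it in brightness, so it covers array noise and real differences together.

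The sample groups, the 33 gene lists, the filter, the floor, the alternatives and the rule for named genes were fixed before the data were examined. A list's median log2 ratio over its measured members was ranked among 10000 random lists of the same size drawn from measured genes matched on mean log2 value in 10 bins. At least 4 measured members were required. A list was called apart at or below the 2.5th or at or above the 97.5th percentile. The percentile describes these 2 arrays only and treats the members as independent, which co-regulated genes are not. The genes named were Slc2a1, the 12 highest and 12 lowest measured genes without a second measured probe set of opposite sign, the 4 leading members of each list called apart in its direction, and the 2 members of every other list with the largest absolute ratio. Other genes named as examples were chosen after their values were seen, and the text says so.

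The steps were tested on simulated data. A second array was made from the control array with the local spread, a scale difference and 200 altered genes among 6114 measured. At the 2-fold call, 0 of 50 genes altered 1.5-fold, 20 of 50 altered 2-fold, 38 of 50 altered 3-fold and 45 of 50 altered 4-fold were recovered. Genes altered 2-fold sit at the threshold itself, so their count does not measure noise. The brightness filter, applied anew to the simulated arrays, left out 4 of the genes altered 2-fold and 11 of those altered 3-fold. Among the 5936 unaltered genes that passed it 1 was called. Among 100 simulated lists of 25 genes each, 5 were called apart with no shift, 47 with a shift of 0.05, 94 with a shift of 0.1 and 100 with a shift of 0.2 log2 units. The alternatives were the deposited values without further scaling, quantile normalization, a loess curve on brightness, no floor or a floor at the 40th percentile, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, 20 brightness bins, and thresholds of 1.5-fold and 3-fold. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.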

Results

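Expression profiles were obtained from 2 pools of A7r5 rat vascular smooth muscle cells, 1 infected with an adenovirus that carried human GLUT1 and 1 with the empty virus. The comparison asks how raising the glucose transporter alters the transcriptome of smooth muscle cells kept in 5.5 mM glucose. Each pool joined the RNA of 3 days and was read on 1 array. The arrays were nearly alike, with a Pearson correlation of 0.993 and a Spearman correlation of 0.990 across the 7962 measured probe sets. No difference below has a replicate check.

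The gene that was overexpressed came first. The rat probe set for Slc2a1, the gene of GLUT1, gave an intensity of 2902 in the control and 3121 in the GLUT1 pool, a log2 ratio of 0.11 and 0.944 times the local spread. The vector carried the human cDNA, and whether rat probes can bind it is not given in the sources used here. The probe set is therefore not used here to check the labels or to measure the transgene. Of the other hexose transporters, Slc2a8 was read at 626 and 704, a log2 ratio of 0.17. Slc2a3 and Slc2a4, chosen after their values were seen, had log2 ratios of 0.00 and -0.05, and a second measured probe set of Slc2a3 gave -0.28. The 4 measured transporters had a median log2 ratio of 0.05, higher than 75.1% of random lists.

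A single gene of the 6114 measured passed the 2-fold size threshold. The simulation also called 1 of 5936 unaltered genes, so the count alone does not set these arrays apart from noise. Slc7a5, which encodes the light chain of the LAT1 transporter for large neutral amino acids, was higher in the GLUT1 pool, at 1643 against 660, a 2.49-fold difference and a log2 ratio of 1.32. This was 9.41 times the local spread of 0.14, and the largest absolute value of any other measured probe set was 4.83. No measured gene was lower by 2-fold. The filter uses the mean of both arrays, so a gene that falls far can drop out by its fall. Below the filter, Ppy had a log2 ratio of -1.92 and Rasl10b of -1.70 or lower, both named after their values were seen. Slc7a5 was read by 1 probe set, 1387280_a_at. Its partner chain Slc3a2, chosen after its value was seen, was read at 6910 and 7364, a log2 ratio of 0.09.

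The next genes in rank, leaving out those with a second measured probe set of opposite sign, lay well below the 2-fold threshold. At the upper end were Rnd2 at a log2 ratio of 0.67, Tmem205 at 0.59, Nop14, a factor of small ribosomal subunit assembly, at 0.59, and Irf1, an interferon-responsive transcription factor, at 0.57. Dio3, the deiodinase that inactivates thyroid hormone, and Wwp2, a ubiquitin ligase, both had log2 ratios of 0.54. Bin3 followed at 0.53, Elfn2 at 0.50, Vps9d1 at 0.49, Adm, which encodes the vasodilator adrenomedullin, at 0.49, and Arhgef7 at 0.48. At the lower end were Sap25 at -0.72, Col14a1, a fibril-associated collagen, at -0.65, Rbms1 at -0.65 and Stmn4 at -0.63. Slc12a9 and Swi5 both had log2 ratios of -0.58. The chemokine gene Cxcl16 had a log2 ratio of -0.56, Slc25a23, a mitochondrial carrier, -0.55, and Ciita, the activator of MHC class II genes, -0.54. Plscr2 at -0.51, Serinc1 at -0.50 and LOC102549828 at -0.50 closed the group. These 23 genes were each between 2.43 and 4.83 times their local spread from the median of probe sets of like brightness. None had a second measured probe set to set beside the first. Left out by that rule, and named after their values were seen, were Prdm2 at -0.56 and Ints1 at -0.52, whose second probe sets gave 0.13 and 0.10. Averaging in the dimmer probe sets brought Elfn2 to 0.06, Arhgef7 to 0.16 and Col14a1 to -0.23. A probe set at the floor on both arrays enters an average as 0, so an average can shrink for that reason alone. The other probe sets of Arhgef7 added nothing to its average.

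**Figure D1:**
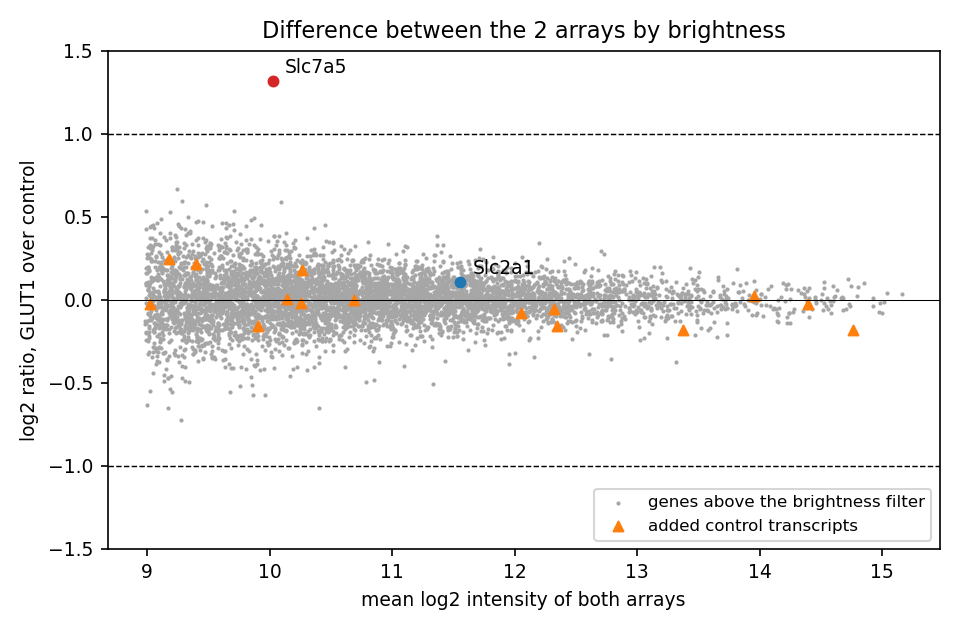
The log2 ratio of GLUT1 over control (vertical axis) against the mean log2 intensity of both arrays (horizontal axis) for the 6114 measured genes, in grey, with 15 probe sets of control transcripts as triangles and dashed lines at 2-fold. Slc7a5 at 1.32 lies alone above the upper line, and Slc2a1 at 0.11 lies within the cloud.

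Over all measured genes the log2 ratio had an SD of 0.14, with 5th and 95th percentiles of -0.21 and 0.23, and 92.5% of genes lay within 0.25 of 0. The local spread was 0.21 for the dimmest measured probe sets, 0.12 at median brightness and 0.073 for the brightest. The manufacturer's control transcripts, bacterial and phage sequences that are added to the hybridisation rather than made by the cells, gave an SD of 0.14 over 15 measured probe sets, with values from -0.18 to 0.24. Several of these probe sets read the same transcript. Genes with at least 2 measured probe sets allowed a check inside the arrays, on the 2 brightest of each gene. In 702 such genes the probe sets pointed the same way in 356, or 50.7% (Wilson 95% interval 47.0 to 54.4, counting error only). The correlation of their log2 ratios across genes was 0.043 (Pearson) and 0.043 (Spearman), where genes are not independent replicates. The SD of a single log2 ratio from these pairs was 0.13, beside an SD of 0.12 among the genes' brighter probe sets. In the 34 genes whose brighter probe set differed by at least 0.25, the second pointed the same way in 20, or 58.8% (interval 42.2 to 73.6).

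**Figure D2:**
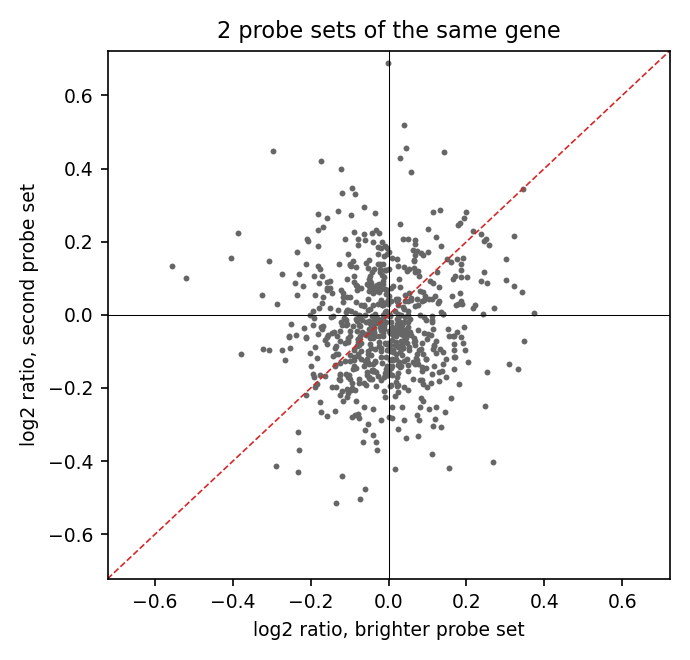
The log2 ratio of the second brightest probe set (vertical axis) against that of the brightest (horizontal axis), with the line of equality dashed. Shown are 702 genes with at least 2 measured probe sets. The points form a round cloud with a correlation of 0.043.

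Genes of carbohydrate metabolism differed by small amounts. The glycolysis list had a median log2 ratio of 0.06 over 20 measured members, higher than 97.9% of random lists, with 13 members above and 7 below 0 and none at 2-fold. Its leading members were Pfkfb1, which sets the level of fructose 2,6-bisphosphate, at 0.32, Hk1, the hexokinase that traps glucose, at 0.20, and the phosphofructokinase subunits Pfkm and Pfkp at 0.19 and 0.18, with Pfkm at 0.12 when its probe sets were averaged. The opposite extreme was Pfkfb2 at -0.46, chosen after its value was seen. The mean of the list lay higher than 92.7% of random lists, which is inside the limits, and among the 11 members left by a filter at the 75th percentile of brightness the median of 0.04 was higher than 94.1% of random lists. In the pentose phosphate pathway Taldo1, encoding transaldolase, was read at 6182 and 7476, a log2 ratio of 0.28, and Rpe at -0.27. The median of the 9 measured members was 0.02. Among genes of the polyol and hexosamine pathways and of glycogen, Gys1, the glycogen synthase of muscle, had a log2 ratio of 0.33 and Oga, the enzyme that removes O-linked N-acetylglucosamine, 0.20, with a median of 0.02 over 11 members. The list for the glucose-sensing factors ChREBP and MondoA and their targets had a median of -0.04 over 4 measured members. It was led by Gpd1 at -0.21 and Bhlhe40 at 0.19. Among the 4 is Mlx, the partner of both factors rather than a target, at 0.025, so fewer than 4 measured targets stand behind this median. Averaging brought Gpd1 to -0.10 only because its other probe set entered as 0, the value given at the floor on both arrays. Txnip, the best known of these targets, was chosen after its value was seen and lay below the brightness filter at 349 and 353.

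Mitochondrial and lipid genes also stayed close to 0. The oxidative phosphorylation list had a median log2 ratio of 0.04 over 40 measured members, higher than 98.9% of random lists, with 31 above and 9 below 0 and none at 2-fold, and its mean of 0.05 was higher than 99.97%. It was led by the ATP synthase subunits Atp5f1e at 0.20 and Atp5f1d at 0.16 and the complex I subunits Ndufb8 at 0.18 and Ndufv2 at 0.16. This list stayed above the upper limit under all alternatives tried, with medians from 0.036 to 0.043. The pyruvate dehydrogenase and TCA cycle list had a median of 0.02 over 28 members, higher than 73.3% of random lists, and its members farthest from 0 were the succinyl-CoA ligase subunits Suclg2 and Sucla2, both at -0.19. Cholesterol synthesis had a median of 0.03 over 18 members, led by Pmvk at 0.33 and Ebp at 0.26. Fatty acid synthesis had a median of 0.06 over 13 members, higher than 94.5% of random lists, with Scd2 at -0.16 and Elovl6 at 0.13. With averaged probe sets its median was 0.01, higher than 55.9%. Fatty acid oxidation had a median of 0.03 over 15 members, with Eci1 at 0.28 and Etfdh at 0.25. Averaging brought Eci1 to 0.14 only because its other probe set entered as 0, the value given at the floor on both arrays.

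**Figure D3:**
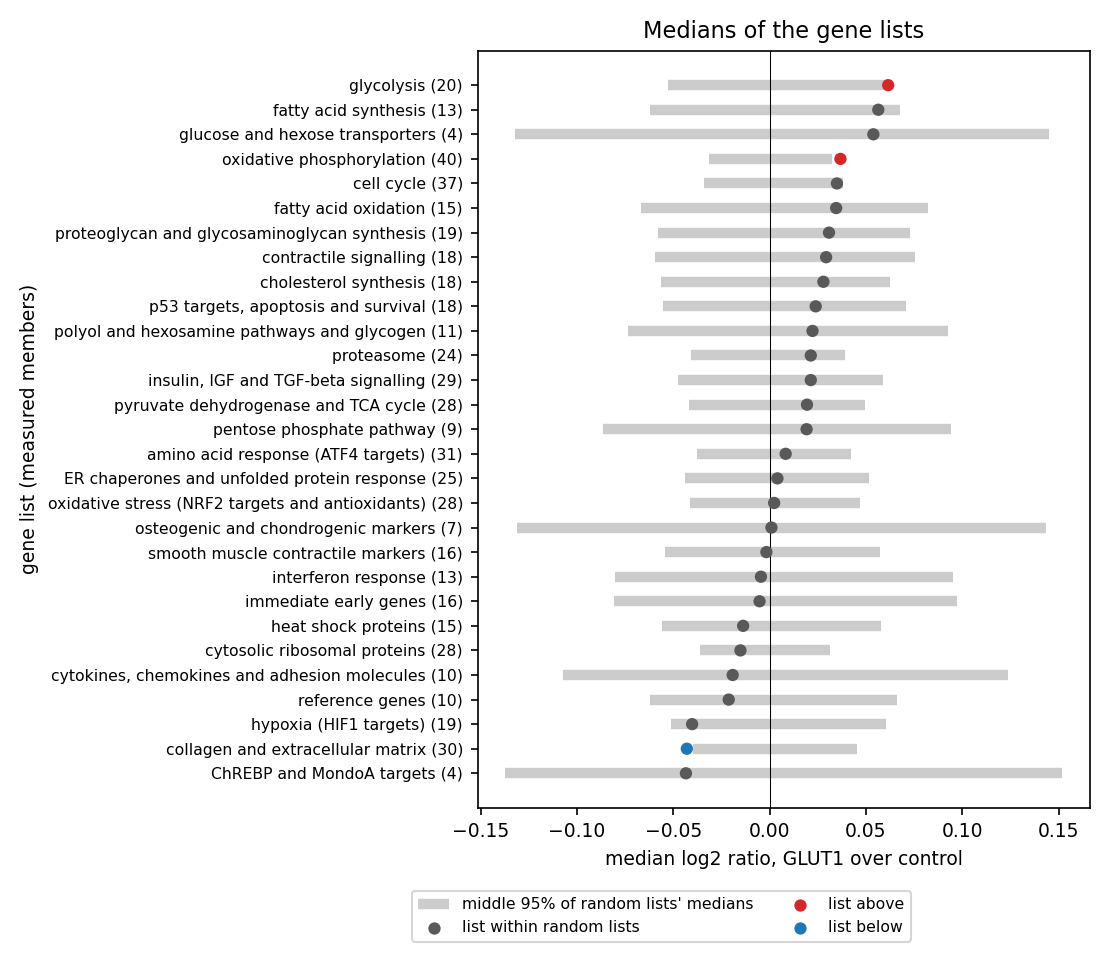
The median log2 ratio of GLUT1 over control (horizontal axis) for 29 gene lists (vertical axis, measured members in brackets), with grey bars for the middle 95% of the medians of random lists matched on brightness. Glycolysis at 0.06 and oxidative phosphorylation at 0.04 lie above their bars and collagen and extracellular matrix at -0.04 lies below.

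Of 22 smooth muscle contractile markers on the array, 16 were measured and 6 lay below the brightness filter, among them Myh11, the smooth muscle myosin heavy chain, at 227 and 228. Acta2, the smooth muscle actin, was read at 16303 and 16687, Tagln at 7153 and 7369, and Cnn1 at 2942 and 3114, all, like Myh11, chosen after their values were seen. The contractile marker list had a median log2 ratio of 0.00 over 16 measured members, with 8 above and 8 below 0. Its members farthest from 0 were Actg2, the enteric smooth muscle actin, at -0.21 and Smtn at 0.19. In contractile signalling the median was 0.03 over 18 members, higher than 74.1% of random lists, while the mean of -0.02 was higher than 19.1%. The farthest were subunits of myosin phosphatase, which relaxes smooth muscle: the catalytic Ppp1cb, at 7983 and 6235, had a log2 ratio of -0.36, and the targeting Ppp1r12a -0.27, or -0.08 when its probe sets were averaged. With a filter at the 75th percentile the list's median turned to -0.03 over 10 members. The mean there, -0.08, was higher than 0.71% of random lists, outside the limits.

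The collagen and extracellular matrix list had a median log2 ratio of -0.04 over 30 measured members, lower than all but 2.02% of random lists, with 17 below and 13 above 0 and none at 2-fold. Leading this direction were the basement membrane genes Nid1 at -0.33, Col18a1 at -0.20 and Lamb1 at -0.17, with the fibrillar collagen gene Col5a2 at -0.14. Nid1 had a second probe set of opposite sign, and its average was -0.14. Averaging brought Col18a1 to -0.07 and Col5a2 to -0.09. The opposite end held Col4a2 at 0.25 and Lamb2 at 0.25, chosen after their values were seen. The mean of the list, -0.01, was higher than 19.1% of random lists, and the median lay inside the limits, at percentiles from 4.7 to 45.7, with no filter, with a filter at the 75th percentile and with averaged probe sets. Genes of proteoglycan and glycosaminoglycan synthesis had a median of 0.03 over 19 members, with Hspg2, encoding perlecan, at 0.37 and Acan, encoding aggrecan, at -0.35.

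Most inflammatory genes were dim on both arrays. Of 44 cytokine, chemokine and adhesion genes on the array, 34 lay below the brightness filter. The 10 measured had a median log2 ratio of -0.02, with 4 above and 6 below 0, led by Cxcl16 at -0.56 and Nfkbia, the inhibitor of NF-kappa-B, at -0.25. Il6 and Icam1, chosen after their values were seen, had log2 ratios of -0.09 and -0.01. In the interferon list the median was 0.00 over 13 measured members, with 6 above and 7 below 0. Irf1 at 0.57 and Tap1, a peptide transporter of antigen presentation, at 0.43 led it, and Tap1 came to 0.08 when its probe sets were averaged.

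Stress programmes gave medians near 0. The list of amino acid response genes controlled by ATF4 had a median log2 ratio of 0.01 over 31 measured members, and without Slc7a5 it was 0.01 over 30. Next to Slc7a5 in this list was Sars1, the seryl-tRNA synthetase, at 0.18. With Slc7a5 the mean of the list lay higher than 99.7% of random lists, while its median lay higher than 59.9%. ER chaperones had a median of 0.00 over 25 members, with Herpud1 at 0.27 and Edem1 at -0.20. Hypoxia genes had a median of -0.04 over 19 members, lower than all but 6.11% of random lists, although Adm had 0.49. Kdm3a was at -0.16. Antioxidant genes had a median of 0.00 over 28 members, with the glutathione enzymes Gsr at 0.30 and Gss at 0.16. Heat shock genes had a median of -0.01 over 15 members, with Hspb6 at 0.29 and Dnajb4 at 0.10. Immediate early genes had a median of -0.01 over 16 members, with Junb at 0.31 and Ier2 at 0.30.

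Growth and maintenance genes showed no 2-fold member. The cell cycle list had a median log2 ratio of 0.03 over 37 measured members, higher than 96.6% of random lists, with 21 above and 16 below 0, and the spindle checkpoint genes Mad2l1 at -0.24 and Bub1b at 0.20 were farthest from 0. In the p53, apoptosis and survival list, with a median of 0.02 over 18 members, Mcl1 was at -0.26, or -0.16 when its probe sets were averaged, and Phlda3 at 0.24. Insulin, IGF and TGF-beta signalling had a median of 0.02 over 29 members, with Ltbp2 at 0.30 and the inhibitory Smad7 at -0.30, or 0.09 when its probe sets were averaged. Cytosolic ribosomal proteins had a median of -0.02 over 28 members, with Rpl21 at -0.23 and Rpl24 at -0.22. Proteasome genes had a median of 0.02 over 24 members, with Psma3 at -0.22 and Psmc3 at 0.14. Reference genes had a median of -0.02 over 10 members, with Hprt1 at -0.13 and Polr2a at 0.10. Across the 29 lists with at least 4 measured members, 2 lay above and 1 below the limits, where 1.45 would be expected by chance from independent lists.

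Markers of other cell types were mostly dim. Of 10 endothelial genes 1 was measured, Esam, at a log2 ratio of -0.28. Of 16 leukocyte genes 3 were measured, among them C1qb, read at 1352 and 1014, at -0.41 and Cd14 at 0.18. Of 12 epithelial and adipocyte genes 1 was measured, the keratin gene Krt8, bright at 6193 and 6500 with a log2 ratio of 0.07. Of 26 skeletal muscle genes 3 were measured, among them Acta1, read at 2339 and 2240, at -0.06 and Mef2c at 0.04. Osteogenic and chondrogenic markers had a median of 0.00 over 7 measured members, with Acan at -0.35 and Enpp1 at 0.32.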

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

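Probe set 1389120_at, which has no gene in the annotation used here and so entered no gene comparison, was brighter on the GLUT1 array, at 428 against 191, a log2 ratio of 1.16. It was set aside because a probe set outside the gene comparisons exceeded the control array by 2-fold. Its mean brightness lay below the filter.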

How the results depend on the processing

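No paired analysis was possible because each group has 1 array. The deposited values were already equalised, so leaving out the scaling and quantile normalization moved values little and say little about stability. Slc7a5 kept a log2 ratio between 1.316 and 1.317 in every setting where it passed the filter, and Slc2a1 between 0.104 and 0.106. Each of these genes is read by 1 probe set above the floors. Floor, filter and averaging could therefore not alter the 2 ratios, and their constancy says little about stability. The count of 1 gene higher and 0 lower became 4 and 4 at 1.5-fold, 0 higher at 3-fold and, with no filter, 5 and 4. It became 0 higher with a filter at the 75th percentile, which leaves Slc7a5 out for its brightness, and 1 lower with a floor at the 40th percentile. A threshold of 5 times the local spread, chosen after seeing the data, gave the same counts. It could give no others, with Slc7a5 at 9.41 and no other measured probe set beyond 4.83, and says nothing about stability. Probe set pairs counted as same-direction made up 42.7% with no filter, where many values sit at the floor. A ratio of 0 was counted there as a direction of its own, so this share does not measure agreement. Among list medians, collagen and extracellular matrix was no longer apart with no filter (0), a filter at the 75th percentile (-0.0383) or averaged probe sets (-0.0241), and glycolysis with a filter at the 75th percentile (0.0426). Lists that passed the limits elsewhere were the cell cycle with quantile normalization (0.0416) or a filter at the 75th percentile (0.050), hypoxia with no floor (-0.0499) or averaged probe sets (-0.0641), and fatty acid oxidation with no filter (0.0599). Inside the limits, medians moved by over their bootstrap SD for polyol and hexosamine pathways with no filter (-0.034), cholesterol synthesis (-0.0262) and contractile signalling (-0.0298) with a filter at the 75th percentile, and fatty acid synthesis (0.00986) and p53 targets (-0.0312) with averaged probe sets. The causes were not tested. The other 242 list values kept their side of the limits, and 8 of 704 values of single genes moved by more than the SD of a single log2 ratio from the probe set pairs, all of them with averaged probe sets. Some of these, such as Arhgef7 and Eci1, shrank because their other probe sets entered as 0, the value of probe sets at the floor on both arrays. Most named genes have 1 probe set, so averaging could not move them, and changing the filter leaves a gene's ratio as it is. The share of 704 is therefore no measure of stability. Noise limits what can be seen in lists: in the simulation 47 of 100 lists shifted by 0.05 were called.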

Other observations

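Tests chosen after the result was seen were those of Slc7a5, of the cytosolic ribosomal proteins, of the correlation between probe sets and of families by symbol. The tests of subunits outside the list, of mitochondrial ribosomal proteins and of the control transcripts were written down before their results. Genes for mitochondrial ribosomal proteins, which translate the subunits encoded in mitochondrial DNA, had a median log2 ratio of 0.06 over 71 measured members, higher than 99.97% of random lists, with 47 above and 24 below 0. Mrpl14 at 0.39, Mrps31 at 0.35, Mrpl37 at 0.32 and Mrpl54 at 0.30, named after their values were seen, led them, and no member reached 2-fold. Over the alternatives of scaling, floor, filter and probe set averaging their median ran from 0.054 to 0.060, and its percentile never fell below 99.5. Among 29 symbol families with at least 15 measured genes, the Mrps genes (0.07 over 26 members) were the only family with a median outside the limits, where 0.725 families above would be expected by chance. The Mrpl genes had a median of 0.03 over 45 members, inside the limits, but a mean of 0.049, higher than 99.16% of random lists, beside 99.19% for the mean of the Mrps genes. These 2 families make up the 71 mitochondrial ribosomal genes above. The family comparison therefore repeats that result on the same arrays and is no separate support.

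Some probe sets beyond 2-fold lay outside the measured genes. Probe set 1394225_at, with no listed gene, passed the brightness filter. It was read at 774 in the control and 383 in the GLUT1 pool, a log2 ratio of -1.01 and -4.83 times the local spread. Probe set 1374094_at, also with no listed gene but below the filter, was read at 455 and 224, a log2 ratio of -1.02. Below the brightness filter, and named after their values were seen, Ppy was read at 774 and 205 and Rasl10b at 570 and 146. Hcn4, a pacemaker channel gene chosen likewise, was read at 154 and 443, at least 2.53-fold brighter because its control value was at the floor. In all, 8 of the 4297 genes below the filter passed 2-fold, 4 each way. The 4 lower ones exceeded the filter's intensity of 507 on the control array.

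Slc7a5 stood apart from every other measured probe set. It lay at 9.41 times its local spread, against at most 4.83 for the others. That argues against noise as wide as the local spread of measured probe sets of like brightness. The gene was picked for its size, and the comparison leaves out genes below the filter. Larger differences occurred there, with Ppy at a log2 ratio of -1.92, so rarer and wider noise is not excluded. An ATF4 response that moves its targets alike is argued against too, since the other 30 measured targets had a median log2 ratio of 0.0065 (bootstrap 95% interval -0.022 to 0.026) and the highest of them reached 0.18. A fault of its probes on 1 array, or in 1 pool, stays open because only 1 probe set names the gene. A response of this gene to GLUT1 also stays open and untested, and 1 array per group cannot separate it from any other difference between the pools.

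The small rise of the oxidative phosphorylation list may be part of a wider pattern or chance. Chance choice of members is not excluded, as 24 measured subunit genes outside the list had a median log2 ratio of 0.027, higher than 87.3% of random lists, which is inside the limits. Their mean of 0.041 was higher than 98.15%, outside the limits, so the answer depends on the summary used. A shift of short abundant mRNAs was left undecided by the rule used. The cytosolic ribosomal proteins had a median of -0.015, below the 0.037 of the oxidative phosphorylation list by less than the SD of 0.084 among their members, which went both ways. That SD describes single genes and not a median. The bootstrap SDs were 0.018 for the ribosomal median and 0.015 for the other. The ribosomal list, higher than 23.7% of random lists, did not share the rise. A general rise of nuclear-encoded mitochondrial mRNAs passed its test with a median of 0.060 for mitochondrial ribosomal proteins, yet the TCA cycle list, higher than 73.3% of random lists, did not stand apart. It remains a hypothesis about small shifts, with list medians of 0.06 log2 units or less and 0.07 for the Mrps genes. A comparison with random lists takes genes as independent, and 1 pool per group does not separate GLUT1 from other differences between the pools.

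The near absence of agreement between probe sets of a gene goes with noise of single probe sets as the main content of the log2 ratios. The correlation over 702 genes was 0.043 (95% interval -0.031 to 0.12, genes taken as independent). The control transcripts varied as widely as genes of like brightness, with a root mean square of 1.22 times the local spread over 15 probe sets. Several of these probe sets read the same transcript, so they are not 15 independent controls. Being added to the hybridisation, they do not cover noise from RNA isolation, labelling or pooling. Both results are consistent with differences between the pools that are, for most genes, below what 1 array each can resolve. The 3′ to 5′ intensity ratio of GAPDH was 1.16 in the control and 1.24 in the GLUT1 pool and that of beta-actin 1.26 and 1.20, so they moved in opposite directions.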
